A study of Homo sapiens with 6 samples.

How the data were processed

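RNA bound to the protein SIRT6, a nuclear NAD-dependent deacylase, was measured by RNA immunoprecipitation followed by sequencing (RIP-seq) in a human breast cancer cell line that the labels call 231. In RIP-seq an antibody pulls a protein and its RNA out of a cell lysate, and the recovered RNA is sequenced beside RNA of the lysate before the pull-down, called the input. The labels name 6 samples. They are an input and a SIRT6 immunoprecipitation (IP), each under a plain title and under titles ending in dedup and filtlowGC. The labels do not say what these endings stand for or that they mark separate cultures, so each sample was a group of 1 and none was treated as a replicate. The table used here has columns for 2 of the samples, the plain SIRT6 and the plain input. The other 4 samples have no column in it, and the versions of the libraries were not compared here.

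Per the labels' protocols, RNA was extracted with TRIzol and stranded mRNA libraries were made with a kit that tags each cDNA molecule with a random barcode, and were sequenced as read pairs on an Illumina instrument. The same protocol text describes immunoprecipitation with antibodies against Ago2 or IgG and a PCR readout, while the series title, its design text and the sample titles name SIRT6. The libraries are called SIRT6 here as the titles have it. The 6 samples include no IgG library, so RNA that sticks to beads or antibody was not measured separately. The submitters' processing notes name Trimmomatic 0.36, bedtools, deepTools and HOMER. The aligner, the read counter with its strand setting, the genome build, and whether reads sharing a barcode were collapsed in the plain libraries are not given in the sources used here.

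Per the file headers, the authors' deposited table gives for each gene an RPKM value, which is reads divided by gene length and by library size, in each of the 2 libraries. It also gives, per the file headers, the authors' p-value and the false discovery rate made from it, and the authors' log2 ratio of SIRT6 over input. The other numeric column used, per the file headers, is the gene length in nucleotides, which the authors' RPKM was divided by. The table holds 6039 genes. The highest deposited p-value was 0.049 and the lowest deposited log2 ratio was 1.0005, so the table holds genes past those limits only, and a gene that is lower in the SIRT6 library cannot be read from it. The ratio of the deposited rates to the p-values corresponds to 16062 tested genes, of which the listed genes are 37.6%. By the same ranks, 3281 unlisted genes had a p as low as the last listed gene.

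From the deposited RPKM and length, each value was a whole multiple of the worth of 1 read, within a tolerance of 0.01 reads, which gave the read count of every listed gene and the library totals behind the authors' RPKM. The SIRT6 total was 5903475 reads and the input total was 4097077 reads. Over listed genes with input reads, the authors' log2 ratio differed from the log2 ratio of their RPKM values by a median of -0.003. The difference was at most 0.138, so both ratios used the library totals without a correction for composition. A large share of SIRT6 reads on some genes lowers the RPKM of all others under this scaling. Folds here are ratios of RPKM, with an exact 95% interval (Clopper-Pearson) from the 2 read counts. A gene with 0 reads in the input was set against a floor of 3 input reads, which is 0.732 RPM there and would be 0.508 RPM in the SIRT6 library, and written as at least that fold. Intervals and floors cover counting error only. They leave out the spread between cultures and any reads copied from a single molecule.

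The log2 ratio used for ranks, lists and counts was log2((SIRT6 RPKM + 1)/(input RPKM + 1)), and it understates the ratio of genes with low values. A gene counted as 2-fold or more higher when this was 1 or more and its higher RPKM was at least 1. With 1 library per group there was no test. For each of 28 gene lists, the members found in the table were counted. For lists with at least 5 listed members of mean RPKM 1 or more, the median log2 ratio was placed among 10000 random lists of the same size, drawn from the listed genes and matched on mean RPKM in 10 bins. This percentile describes the 2 libraries. Named genes were chosen by a rule. It took HOXC-AS3 and SIRT6, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes of at least 200 nt with an RPKM of 5 or more, and the 2 highest and 2 lowest listed members of each list with mean RPKM of at least 1. It also took the 10 genes with the highest RPKM in each library and the 5 long noncoding RNA genes with the highest log2 ratio. Some genes that the rule takes are not reported here. Groups, lists, the rule, the pseudocount and the alternatives were fixed before the data were examined, except where the text says otherwise. The planned pair was that of the dedup libraries, with the plain pair as the stated fallback, and the fallback was used.

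Gene symbols and types came from a RefSeq table for GRCh38.p14. Of the names, 4915 were RefSeq symbols, 252 matched through a synonym and 872 did not match. A list member matched by synonym alone and not the same gene was left out. Chromosome positions are those of the authors' deposited table. They overlapped the RefSeq span of the same gene in 4914 of 4915 cases, though no source names the build. The reads were also run through an exact test for 2 libraries under assumed coefficients of variation between replicates, a check chosen after the data were seen. It compares these 2 libraries, not the conditions. The interval and this test were tried on simulated reads, with library totals set below those of the 2 real libraries. The interval held the true fold in 96.0% of 6039 genes simulated with counting error alone. For the test, a coefficient of variation of 0.1 was used both to make the reads and to run it. Only genes of 50 to under 20000 reads were tested. It called 4.30% of 4349 unchanged genes, 90.7% of 86 genes changed 2-fold and 100% of 94 genes changed 4-fold. The low share of unchanged genes called follows from that match. It does not carry over to these data, whose spread between replicates is unknown. Alternatives were pseudocounts of 0.1 and 5, other filters on RPKM, leaving out mitochondrial, small RNA and short genes, and subtracting medians within 20 bins of gene length for the lists. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.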

Results

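RIP-seq of SIRT6 was compared with input RNA in the breast cancer cell line labelled 231, with 1 library of each kind and no replicates. The series concerns HOXC-AS3, a long noncoding RNA of the HOXC homeobox gene cluster, and asks whether it is bound by SIRT6 and bears on glycolysis. The SIRT6 library held 5903475 reads and the input library 4097077 reads. The authors' deposited table listed 6039 genes, each with a log2 ratio of at least 1.0005 in the SIRT6 library over input. The listed genes had a median of 147 reads in the SIRT6 library and 29 in the input, and 1619 of them had fewer than 10 input reads.

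PLEC, KMT2D, TNRC18, C22orf46 and NBPF8 were among the 12 genes with the highest ratio in the SIRT6 library over input. PLEC, which encodes the cytoskeletal linker plectin, was 20.02-fold higher (95% counting interval 19.2 to 20.9). KMT2D, a histone H3 lysine 4 methyltransferase, was 23.6-fold higher (20.8 to 27.0). HOXC-AS3 was 14.6-fold higher (5.49 to 54.7), on few reads. The other HOX genes looked up and the ribosomal proteins were absent from the table. Of 26 glycolysis genes 9 were listed, which is 34.6%. Of all protein-coding genes, tested or not, 15.8% on chromosome X to 30.4% on chromosome 22 were listed. Of the genes tested by the authors 37.6% were listed, but how many of the 26 were tested is unknown.

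The listed genes took 69.5% of the SIRT6 reads (95% exact binomial interval 69.46 to 69.54) and 15.002% of the input reads (14.97 to 15.04), a ratio of 4.63. A larger SIRT6 share was fixed by selection, since the authors' table holds only genes at least 2-fold higher. The 100 listed genes with the most SIRT6 reads took 26.5% of that library and 4.16% of the input. The median log2 ratio with a pseudocount of 1 was 1.24, with quartiles of 0.87 and 1.73. By this measure 4015 genes were 2-fold or more higher in the SIRT6 library, 968 were 4-fold or more and 149 were 8-fold or more higher. No gene could be lower, because the table holds higher genes only. The counting interval of the fold lay above 1 for 5975 genes and above 2 for 3590 genes. With a pseudocount of 5 the 2-fold count was 1692 and the median 0.63. The authors' p-values lay closest to an exact test of the 2 libraries with an assumed coefficient of variation of 0.1, which called 5954 of 6021 genes, and at an assumed 0.4 it called 3109. The first count was near its maximum by selection, since the table holds only genes past the authors' p limit.

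**Figure D1:**
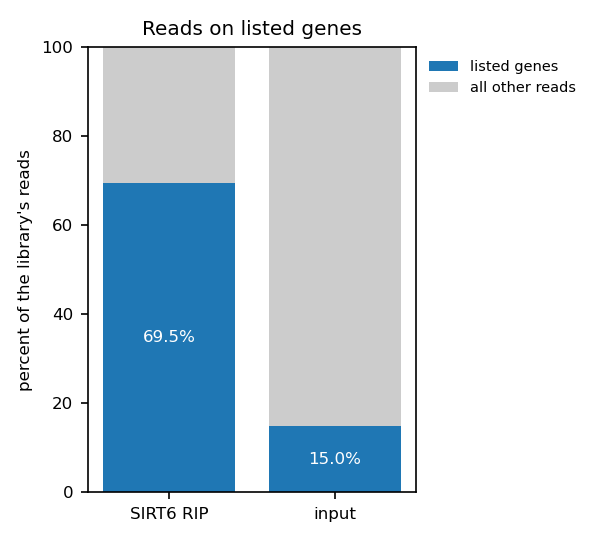
Share of each library's reads, in percent, on the listed genes (blue) and on everything else (grey), for 1 SIRT6 library and 1 input library. The listed genes took 69.5% of the SIRT6 reads and 15.002% of the input reads, and the direction follows from their selection by the authors.

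HOXC-AS3 lies at chromosome 12, 53981509 to 53985519, on the minus strand, with 3109 nt of exons in the authors' deposited table. It had 84 reads in the SIRT6 library and 4 in the input, or RPKM values of 4.58 and 0.314. Its log2 ratio was 2.09 with the pseudocount and 3.83 in the authors' deposited table, where its adjusted p was 3.91e-11. With a pseudocount of 5 its log2 ratio was 0.85. HOXC-AS3 ranked 445 by log2 ratio in the authors' deposited table, 839 with the pseudocount and 1911 by p in the authors' deposited table. Among the 188 listed genes that RefSeq types as long noncoding RNA, HOXC-AS3 ranked 23. In RefSeq, HOXC10 overlaps HOXC-AS3, and HOXC10 was not listed. The strand setting of the counting is unknown, so reads in the part that HOXC-AS3 shares with HOXC10 cannot be told apart. No other listed gene lay within 200000 nt of HOXC-AS3. Of the 15 members of the HOXC cluster list, 1 was listed, HOXC-AS3 itself, and of 40 HOXA, HOXB and HOXD genes 0 were listed. The SIRT6 gene's own RNA was not listed. Among the 7 sirtuins 1 was listed, SIRT7, a nucleolar family member, at 6.002 RPKM in the SIRT6 library and 1.63 in the input (3.69-fold, 2.63 to 5.29).

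**Figure D2:**
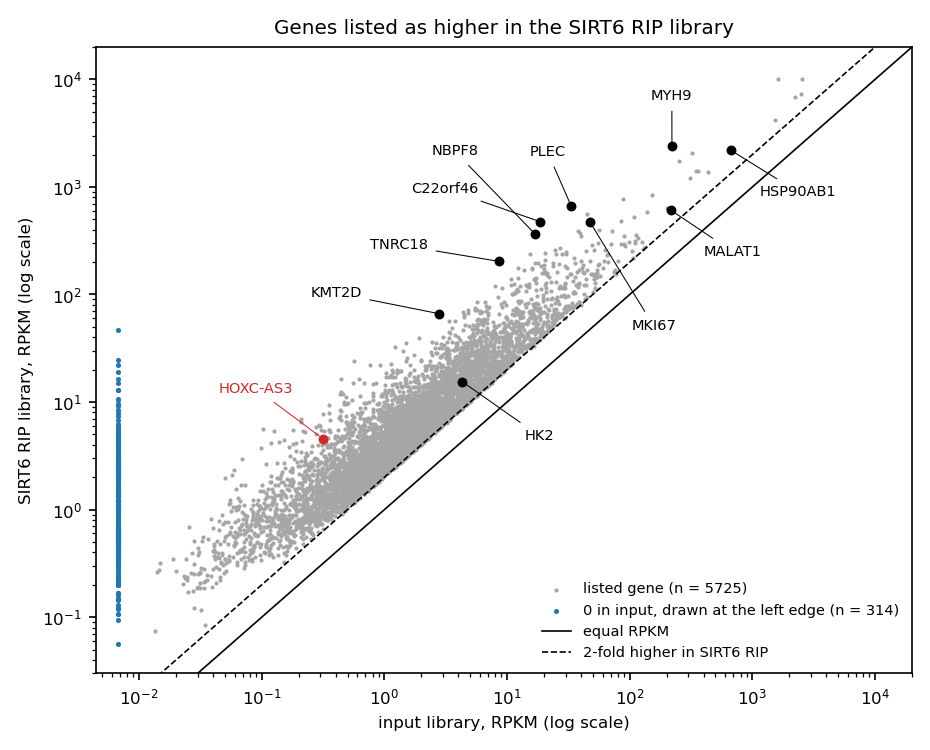
RPKM of each listed gene in the input library (horizontal, log scale) and in the SIRT6 library (vertical, log scale), 1 library each, with HOXC-AS3 in red and other named genes in black. Points at the left edge are the 314 genes with 0 input reads. The solid line marks equal RPKM and the dashed line 2-fold, and the points lie above the dashed line because the authors' table holds such genes only.

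With a pseudocount of 1 the highest log2 ratio belonged to C22orf46, which RefSeq types as a transcribed pseudogene, at 474.5 RPKM in the SIRT6 library against 18.7 in the input (25.4-fold, 23.01 to 28.1). TNRC18, a large protein with a chromatin-binding domain, had 203 against 8.60 RPKM (23.6-fold, 21.5 to 26.0). PLEC had 666 against 33.3 RPKM and KMT2D had 66.2 against 2.80. PITPNM3 had 32.5 against 1.22 RPKM and BAHCC1 had 35.8 against 1.49, with log2 ratios of 3.92 and 3.89. C19orf68, now named ZSWIM9, had 239 against 15.5 RPKM and a log2 ratio of 3.86. NBPF8, NBPF26 and NBPF10 had log2 ratios of 4.33, 3.995 and 3.81. The order depends on the pseudocount. Genes above C22orf46 by fold included NBPF26 at 42.3 (25.1 to 77.8) and PITPNM3 at 26.7 (20.3 to 35.7). NBPF25P, named after its value was seen, was also above it at 28.6 (16.2 to 55.7) on 494 against 12 reads. The NBPF genes are near-identical copies, and how the authors' counting split reads between them is unknown, so the value of each is uncertain. RP11-182J1.12 and RP4-791M13.5 had 55 and 31 SIRT6 reads and 0 input reads, which makes them at least 12.7-fold and 7.17-fold higher against the floor of 3 input reads.

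MYH9 and HSP90 chaperone genes were among the most abundant listed RNAs of the nuclear genome. MYH9, the heavy chain of non-muscle myosin IIA, had the highest RPKM of these in the SIRT6 library, at 2416 in the SIRT6 library and 221 in the input (10.9-fold, 10.7 to 11.2). The chaperone genes HSP90B1 and HSP90AA1 were 6.50-fold (6.33 to 6.67) and 6.96-fold (6.77 to 7.16) higher, and HSP90AB1 was 3.28-fold higher (3.20 to 3.36). NCL, which encodes the nucleolar protein nucleolin, had 1416 against 349 RPKM, and ANP32B had 1413 against 358. RP11-872D17.4 was among the 10 listed genes with the highest RPKM in the input, with 1364 RPKM in the SIRT6 library and 437 in the input. MT-TR, MT-TG, MT-TY and MT-TC, which are mitochondrial transfer RNA genes, and MT-ND3 had the highest RPKM of all listed genes. MT-TR had 10179 against 2535, MT-TG 10141 against 1622, MT-TY 7351 against 2467, MT-TC 6909 against 2208 and MT-ND3 4235 against 1541. The transfer RNA genes are 65 to 68 nt long, and MT-TR and MT-TG directly flank MT-ND3, so reads on them may be shared with their neighbours.

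The list named long genes of membrane and adhesion proteins stood above other listed genes. It also holds genes of other kinds, such as that of the cytoskeletal linker plectin. Its place therefore cannot be credited to membrane and adhesion proteins as a class. Of 25 members 16 were listed, with a median log2 ratio of 2.92, at percentile 100 of random lists, whose central 95% ran from 1.42 to 2.28. PLEC at 4.28 and NAV2, a neuron navigator gene, at 3.64 were its highest members, and NRG1 at 1.04 and PTPRK at 1.37 its lowest. Secreted and extracellular matrix genes had 17 of 35 members listed and a median of 2.22, at percentile 89.2. Their highest members were the collagen genes COL5A1 at 3.40 and COL4A2 at 2.96, and FN1, which encodes fibronectin, was among their lowest at 1.10. Splicing factors had 9 of 42 members listed and a median of 1.93 (percentile 59.6), from SRRM1 at 2.93 and SRRM2 at 2.89 down to SF3B1 at 0.98 and CLK4 at 0.68.

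By their median, cell cycle and mitosis genes stood below other listed genes. Of 31 members 11 were listed, with a median of 1.19, at percentile 0.12, against a central 95% of 1.39 to 2.47. MKI67, the proliferation marker Ki-67, was an exception at 3.31 (10.1-fold, 9.67 to 10.5), as was CENPE at 2.32. MCM3 at 1.84, TOP2A at 1.76 and TPX2 at 1.63, named after their values were seen, were not low either. They exceeded 1.39, the median of all listed genes with mean RPKM of 1 or more. The other members lay below that median, among them MCM6 at 0.93 and BUB1B at 1.05. The medians of the remaining lists with a percentile lay within the central 95% of their random lists. DNA repair had 15 of 34 listed and a median of 1.39 (percentile 13.8), with PRKDC at 2.28, ATM at 1.76, ERCC2 at 1.20 and LIG3 at 0.89. Translation factors had 7 of 33 listed and a median of 1.45 (percentile 5.69), with EIF4G1 at 2.55, EIF3C at 2.11, EIF4A2 at 1.07 and EIF5B at 1.06. NF-kB pathway and target genes had 9 of 23 listed and a median of 1.28 over 8 of them (percentile 2.85), with TNFAIP2 at 2.17, LIF at 2.15, NFKB2 at 1.21 and RELA at 1.14. KRAB zinc finger genes had 27 of 66 listed and a median of 0.92 over 13 of them (percentile 5.87), with ZNF91 at 2.47 and ZNF202 at 1.63.

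Of 26 glycolysis enzymes and glucose or lactate transporters, 9 were listed, with a median of 1.25 (percentile 19.3). HK2 and HK1, hexokinases of the entry step of glycolysis, were 3.59-fold (2.92 to 4.46) and 3.10-fold (2.82 to 3.42) higher in the SIRT6 library. PFKFB3, whose product makes an activator of phosphofructokinase, was 3.87-fold higher (3.09 to 4.87). PFKFB4 had the highest fold of the 9, at 4.65 (2.78 to 8.27) on 114 against 17 reads. The log2 ratios were 1.73 for PFKFB3, 1.63 for HK2, 1.59 for HK1, 1.31 for PFKFB4, 1.25 for PFKL, 1.11 for ENO2, 1.05 for SLC16A3, 0.91 for PFKFB2 and 0.80 for SLC2A3. GAPDH, LDHA, PKM, PGK1, ENO1, ALDOA and SLC2A1 were among the 17 members not listed. HK1, PFKFB4, PFKL, ENO2, SLC16A3 and these 7 unlisted genes were named after their values were seen. Of 20 other hypoxia-responsive genes 4 were listed, BHLHE40 at 1.69, VEGFA at 1.62, KDM3A at 1.48 and P4HA2 at 0.86. Of 21 enzymes of the tricarboxylic acid cycle 4 were listed, among them PC at 1.61, OGDH at 1.16 and SDHA at 1.05. None of 8 pentose phosphate pathway genes was listed.

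**Figure D3:**
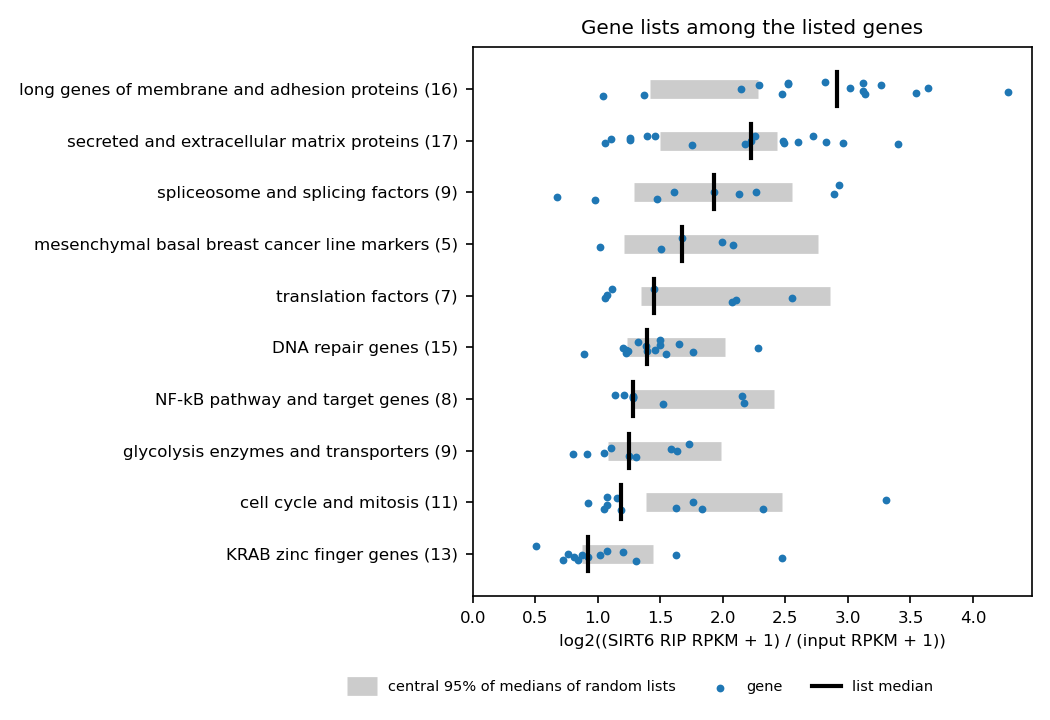
Log2 ratio with a pseudocount of 1 (horizontal) of each listed member with mean RPKM of at least 1 (points), in the 10 gene lists with at least 5 such members, whose number stands in brackets. Black bars are list medians and grey bars the central 95% of medians of 10000 random lists matched on mean RPKM. The median of the list named long genes of membrane and adhesion proteins lies to the right of its grey bar. That of the cell cycle list lies to the left.

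Ribosomal protein, respiratory chain and histone genes were absent from the table. None of 78 cytosolic ribosomal protein genes, 50 mitochondrial ribosomal protein genes, 31 nuclear-encoded respiratory chain subunits or 26 replication-dependent histone genes was listed. Of 31 proteasome subunits 1 was listed, PSMD2 at 1.15. None of 31 small structured noncoding RNAs, 2 mitochondrial ribosomal RNAs or 12 blood cell markers was listed, and 1 of 13 mitochondrial mRNAs, MT-ND3, was at 1.46. Of 20 markers of mesenchymal basal breast cancer lines 5 were listed, with a median of 1.68 (percentile 26.4), among them ZEB1 at 2.08, EGFR at 1.99, KRT80 at 1.02 and MSN at 1.504. Of 16 luminal breast markers 2 were listed, ERBB3 and GATA3. GATA3 was at 0.93 (2.83-fold, 1.52 to 5.66). ERBB3, on 35 against 2 reads, was at 0.67 (12.1-fold, 3.12 to 104). An unlisted gene may have been lower, equal or less than 2-fold higher in the SIRT6 library, or 2-fold or more higher on too few reads to pass the authors' p limit, or not tested.

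From the list of nuclear-retained long noncoding RNAs, set by name, 5 of 20 were listed. RefSeq types its member TUG1 as protein-coding, and the place of these RNAs in the cell was not measured. MALAT1 had 610 RPKM in the SIRT6 library and 215 in the input (2.83-fold, 2.76 to 2.90), and LINC-PINT, TUG1 and PVT1 had log2 ratios of 1.06, 0.84 and 0.82. KCNQ1OT1, named because it completes the count, had 46 SIRT6 and 13 input reads. Of 18 snoRNA host genes 4 were listed, SNHG3, SNHG17, SNHG7 and SNHG4. Among the 5 long noncoding RNAs with the highest log2 ratio were NAV2-AS2 at 3.61, ZSWIM8-AS1 at 2.84, COL4A2-AS2 at 2.82 and SAPCD1-AS1. SAPCD1-AS1 had 16 SIRT6 reads and 0 input reads (at least 3.70-fold against the floor, with an exact lower limit of 2.68-fold). All of these are antisense genes. Because the counting's strand setting is unknown, the reads of each cannot be told apart from those of the gene on the other strand. NAV2-AS2 and NAV2 had log2 ratios of 3.61 and 3.64, and COL4A2-AS2 and COL4A2 had 2.82 and 2.96.

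The lowest log2 ratios among genes of at least 5 RPKM were close to the authors' limit of 2-fold. They ran from 0.80 in FBXW8 to 0.83 in LNX1, with folds of 2.02 (1.48 to 2.80) and 2.04 (1.55 to 2.72). Between them were TRIM65, PIAS3, NCBP1, WWTR1, MARCH6, NCBP3, MTMR12, SNX1, PANK2 and A4GALT. NCBP1 and NCBP3 encode proteins that bind the mRNA cap. The values compare 2 libraries, and no spread between cultures stands behind any of them.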

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

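The tests with no pseudocount and with assumed coefficients of variation were chosen after the data were seen. No paired analysis was possible because each group holds 1 library. The 4015 genes 2-fold or more higher became 1692 with a pseudocount of 5, and stayed within 1.5 times under the other alternatives run, from 2844 at RPKM of 5 or more to 5285 with a pseudocount of 0.1. The median log2 ratio of 1.24 became 1.81 with a pseudocount of 0.1, 0.63 with 5 and 1.91 with none, which follows from the pseudocount pulling low genes toward 0. It was 1.32 at RPKM of 1 or more and 1.65 at 5 or more, where the cause was not tested. HOXC-AS3 at 2.09 ranged from 0.85 with a pseudocount of 5 to 3.87 with none, and its 4 input reads limit it. The exact test called 5954 of 6021 genes under 20000 reads at a coefficient of variation of 0.1, where its p-values lay closest to the authors' and selection fixed the count near its maximum, 5692 at 0.2, 4490 at 0.3 and 3109 at 0.4. For HOXC-AS3 its p was 5.6e-04 at 0.4. Under each alternative run, 2 lists lay outside the central 95%, the list named for long membrane and adhesion genes above and the cell cycle list below. Of named genes, 54 moved by more than their counting interval spans around the reported log2 ratio with a pseudocount of 5, and 9 with 0.1. Not run were the dedup and filtlowGC pairs, which have no columns, the bins of GC content, for which no genome was used, the length bins outside the lists, and rescaling to a common sum or to a median of 0, because over a table of higher genes alone these set the typical listed gene near 0 by construction.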

Other observations

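The gene families were chosen after their values were seen, so their medians describe them and do not set them apart from other genes, while the tests of overlapping genes and of chromosomes were set down before their results. The acetyltransferase genes CREBBP and EP300 were 13.8-fold (12.1 to 15.8) and 9.79-fold (8.37 to 11.5) higher in the SIRT6 library. They stood in a set of 38 listed chromatin regulators, picked with TNRC18, KMT2D and BAHCC1 among them, that ran from 0.26 to 4.41 with a median log2 ratio of 2.65. ARID3B at 0.96 and ARID2 at 1.13 were among its lower members. The 21 listed collagen genes had a median of 1.42, and the 16 with mean RPKM of 1 or more had 2.48. COL7A1 at 3.52 was highest and COL1A2, with 7 reads against 0, was lowest. With the pseudocount, the 8 listed laminin genes ran from LAMA1 at 0.45 to LAMB2 at 2.85. Their median was 2.10, or 2.46 over the 7 with mean RPKM of 1 or more. By fold LAMA1 was the highest of the 8, at 13.2 (3.41 to 113) on 38 against 2 reads, and LAMB2 was at 8.20.

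The 8 listed myosin heavy chains had a median of 1.44, and 3.03 over the 5 with mean RPKM of 1 or more. With the pseudocount, MYH9 at 3.45, MYH3 at 3.10 and MYH10 at 3.03 stood above MYH11 at 0.44 and MYH14 at 0.25. By fold the order differed. MYH7B was highest at 25.3 (6.77 to 213) on 73 against 2 reads. MYH14 was at 9.02 (1.36 to 383) on 13 against 1 reads, and MYH10 at 8.80 (7.98 to 9.73). The 29 listed kinesins had a median of 1.63, with KIF1C highest at 3.33. The 6 listed HSP90 genes, 3 of them pseudogene copies, had a median of 2.20. The 13 listed NBPF genes had a median of 2.87, and the 11 listed GOLGA6 and GOLGA8 genes 1.58. Reads of the last 3 families can be shared between copies. Across 4903 genes of mean RPKM 1 or more, which are not independent replicates, gene length and the log2 ratio had a Spearman's rho of 0.036. The share of genes 4-fold or more higher was 27.01% in the shortest of 5 length groups of about equal size, 8.57% in the next and 29.7% in the longest.

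Of 559 noncoding or unmatched genes that overlap a listed protein-coding gene on the opposite strand, 521 share exon positions with it, and their log2 ratios followed that gene's. Across these genes the rank correlation with the overlapping gene was 0.54 (95% bootstrap interval 0.47 to 0.61), against 0.15 (0.07 to 0.23) with the nearest listed gene that does not overlap. The difference of 0.39 (0.29 to 0.49) exceeded the 0.2 set down for reads of the protein-coding transcript being counted to the noncoding gene, which may therefore account for part of the antisense RNAs in the table. It was 0.44 (0.34 to 0.54) for the 521 pairs that share exon positions and 0.10 (-0.36 to 0.54) for the 38 that do not, too few to set the groups apart. A property shared by the whole region stays open, since the correlation of 0.15 with the neighbour lay between the bounds set for it, and SIRT6 binding both transcripts was not tested.

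The share of protein-coding genes that were listed tended to be larger on gene-dense chromosomes, with exceptions. Chromosome 13, with 2.96 genes per megabase, had 18.3% listed and chromosome 19, with 24.8, had 27.7%. The lowest share was 15.8% on X, at 5.43 genes per megabase, and the highest 30.4% on 22, at 8.88. Over 23 chromosomes Spearman's rho with genes per megabase was 0.57 (permutation p 0.0046, adjusted 0.0093 over 2 relations) and Pearson's r was 0.49 (p 0.014, adjusted 0.029). Without chromosomes 19 and 17, r was 0.47. Larger ratios on such chromosomes, and more of their genes being expressed and tested, could each give this. The chromosome medians of the log2 ratio had a rho of 0.32 with gene density (permutation p 0.14). This rho lay between the bounds set for both explanations, which therefore cannot be told apart. Pearson's r, for which no bounds were set, was 0.15 (p 0.52).

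The ranks behind the authors' deposited rates leave strong unlisted genes. Of the 10 lowest p-values among the 16062 tests 2 belong to listed genes, of the 50 lowest 29, of the 100 lowest 75 and of the 1000 lowest 863. The direction of the unlisted genes was not analysed here.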
